A study of Mus musculus with 4 samples.

How the data were processed

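Lin-cKit+ cells were sorted from mouse bone marrow, uncultured and untreated, and total RNA was amplified by single primer isothermal amplification and labelled with biotin for an Affymetrix whole-transcript 1-colour array, per the labels' protocols. The 2 wild type samples were pools of 3 animals each and the 2 mutant samples were single mice of genotype URE-/+::Msh2-/-, per the labels. Both groups had the same mixed background (R1 embryonic stem cell-derived, Agouti and C57Bl/6).

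The deposited values are log2 signals per probe set, 1 column per sample, for 35556 probe sets, made by the authors before deposit. The log2 scale was read from the values, which lie between 3.18 and 14.45 in all 4 columns, and was not stated in a header. MAS5 and RMA are named in the submitters' processing notes without version, order or role, and which of them made these values is not given in the sources used here, nor is a genome build. The column medians over all probe sets were 7.06 and 7.14 in the wild type pools and 7.14 and 7.18 in the mutant mice, and the quantiles were close but not identical. For arrays, the number of samples limits the precision.

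Probe sets were named from the platform annotation given. It lists 21789 probe sets with 1 gene symbol, 1621 with several and 12146 with none. Probe sets with several or none were not named and stayed out of the tests of genes. Of the named probe sets, 21698 had an identifier in the reference gene table (assembly GRCm38.p6), and 0 symbols changed through it. That table was used only for names and for which genes neighbour each other, and no coordinates are given. Where a gene had several probe sets, the one with the highest mean over the 4 samples was taken, which left 19938 genes. Several probe sets were present for 999 genes. In 297 of them a probe set left aside had a difference of opposite sign, and this was so for 0 of the genes past the threshold.

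Genes were compared with limma (lmFit and eBayes, version 3.58.1 in R 4.3.3) on the values as deposited, two-sided, with no filter on dim genes and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. The fit had 2 residual and 4.33 prior degrees of freedom. Differences are mutant minus wild type on the log2 scale, SE is limma's moderated standard error, and the confidence interval is its 95% interval. Group values are mean ± SD over 2 samples. The wild type pools and single mutant mice were treated as having 1 common spread, although a pool averages animals.

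Gene lists were fixed before the data were examined: 17 lists for testing and 1 of sex-linked genes as a check, with 521 entries, of which 474 were measured (498 distinct genes, 452 measured). They cover PU.1-activated myeloid, stem cell and self-renewal, granulocyte granule, monocyte and dendritic cell, erythroid, megakaryocyte, mast cell with basophil and eosinophil, B cell, T and NK cell, stromal and endothelial, cell cycle, DNA mismatch repair, p53 target, interferon-stimulated, immediate-early and heat shock, acute myeloid leukaemia associated and cytosolic ribosomal protein genes. Each was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, two-sided and adjusted over the 17 lists. Camera with an estimated correlation and fry stood beside it. Msh2 and the other unmeasured entries had no probe set with that symbol alone and were not analysed here.

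The rule for named genes was also fixed before the data were examined. It took Spi1 and Msh2, the 12 genes with the largest rise and the 12 with the largest fall past the threshold whose mutant values both lay outside the wild type range, and the 4 members with the smallest p in each list. It left out predicted and numbered loci, olfactory and vomeronasal genes, immunoglobulin and T cell receptor segments, histone, small RNA and microRNA genes, which removed 10 genes that rose and 2 that fell. Naip6, Clec10a and Gpr141 and the further list members named in the text were chosen after their values were seen.

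The test was checked on simulated data with 19938 genes and variances drawn from limma's fitted prior, for mutant against wild type. It recovered 4% of genes changed by 0.5 on the log2 scale, 90% of those changed by 1, 98% by 1.5 and 100% by 2, with 7 false calls among 153. Of 200 simulated lists with no shift, 4 had a camera p under 0.05. The simulated genes varied independently, so this does not check camera where genes of a list vary together. The simulated samples also varied independently, with 1 common spread for pools and single mice. The false calls thus check limma only where its own model holds. Camera was simulated with the preset correlation only. In the lists past the threshold the estimated correlation between genes ran from -0.04 (T and NK cell) to 0.71 (interferon-stimulated).

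Alternatives planned before the data were examined were quantile normalization, centring on the median of all probe sets, a filter at the median level, a prior variance that follows the mean level, a robust prior, the mean of all probe sets of a gene, all probe sets of the table, the replicate number as a block, each sample left out in turn, and a 2-fold limit. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.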

Results

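Gene expression was measured in 4 samples of mouse bone marrow cells sorted as Lin-cKit+, that is, cells without the surface markers of mature blood lineages and with the stem cell factor receptor Kit. This gate holds blood stem cells and early progenitors. The wild type group had 2 samples, each a pool of 3 animals. The mutant group had 2 samples, each from 1 preleukemic mouse with the genotype URE-/+::Msh2-/-. These mice carried 1 copy of a deletion of the upstream regulatory element (URE), an enhancer of Spi1, which encodes the myeloid transcription factor PU.1. They also lacked Msh2, a DNA mismatch repair gene. Values were log2 signals of probe sets on a whole-transcript array, and 19938 genes were tested. Over these genes the correlation was 0.997 between the wild type pools, 0.995 between the mutant mice, and 0.993 to 0.995 between samples of different genotype. The per-sample SD was 0.123 within wild type and 0.156 within mutant. A pool of 3 animals averages differences between animals that a single mouse does not.

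The comparison asked how expression in progenitor cells differed before leukemia in mice with a deleted copy of the Spi1 enhancer and no Msh2. Spi1 itself was measured at 12.25 ± 0.02 in wild type and 12.10 ± 0.09 in mutant (log2, SD, n = 2 each). The mutant mean corresponded to 90.0% of the wild type mean, with a 95% confidence interval of 78.3% to 103.5%. Both mutant mice lay below both wild type pools, and the difference of -0.15 (SE 0.08) did not pass limma's test (adjusted p = 0.358). It was -0.05 when each array was centred on the median of its tested genes, a setting chosen after the data were seen, and -0.21 when each array was centred on the median of all probe sets. With 1 sample left out it lay between -0.21 without mutant mouse 1 and -0.09 without mutant mouse 2. Msh2 was not analysed here, because no probe set had Msh2 as its single gene symbol in the annotation used.

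Expression differed at 49 genes, of which 23 were higher and 26 were lower in the mutant (limma, adjusted p under 0.05). At an unadjusted p under 0.05 the balance was different, with 804 genes higher (4.03%) and 3042 lower (15.3%). Differences of at least 2-fold made up 13 of the higher and 12 of the lower genes. Genes that rose included Haao, an enzyme of tryptophan breakdown, Naip5, an inflammasome sensor of bacterial flagellin, Hcar2, the niacin receptor, and the cytokine Osm (oncostatin M). Genes that fell included the macrophage lectin Mgl2, Tek, the angiopoietin receptor of blood stem cells and endothelium, the B cell adaptor Blnk, and Anpep, a peptidase on the surface of myeloid cells.

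The largest rise among the 24 named genes past the threshold was in Tmem178, from 8.13 ± 0.004 in wild type to 9.86 ± 0.45 in mutant (log2, SD, n = 2 each), a difference of 1.73 (SE 0.19, limma adjusted p = 0.0433). Haao rose from 8.27 ± 0.05 to 9.81 ± 0.25, or 2.92-fold (limma adjusted p = 0.0229). Naip5 rose 2.79-fold (limma adjusted p = 0.0292). Its near-identical relative Naip6 differed by 1.18 and did not pass (limma adjusted p = 0.0733), and the array probes were not checked for sharing between these copies. Hcar2 rose by 1.29 on the log2 scale, Ifnz, a type I interferon gene, by 1.06, and the long non-coding RNA Firre by 1.06. The collagen-binding integrin subunit Itga1 rose by 1.05, Osm by 0.93, Ints6l by 0.87, the metalloprotease Adamts10 by 0.86, Otogl by 0.70 and Depdc7 by 0.68.

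The largest fall among the named genes past the threshold was in Mgl2, from 10.34 ± 0.08 in wild type to 8.47 ± 0.19 in mutant, or 3.66-fold lower (limma adjusted p = 0.0108). Its relative Clec10a differed by -0.73 and did not pass (limma adjusted p = 0.0612). The log2 difference was -1.24 for the actin regulator Eps8 and for the MAP kinase phosphatase Dusp16, -1.20 for Blnk and -1.10 for Anpep. Tek fell from 8.26 ± 0.12 to 7.25 ± 0.02, a difference of -1.01 (SE 0.09, limma adjusted p = 0.0229). It was -1.04 for the lipid desaturase Scd1, -1.07 for Lrig3, -1.01 for Oosp1 and -0.93 for the caveola protein Cavin2. Gpr141b fell by 1.08, while its relative Gpr141 differed by 1.04 in the other direction without passing (limma adjusted p = 0.0631). Rps4l, a copy of the ribosomal protein gene Rps4x, fell by 1.08, and as with Ifnz, which belongs to a gene family, sharing of probes with related copies was not excluded.

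In all 49 genes both mutant values lay outside the range of the wild type values on the same side. This held for 53.8% of all genes tested, against 33.3% expected by chance for 2 samples against 2. For the 49 genes it follows largely from the call itself, and the naming rule required it of the 24 named ones. It is thus no separate support for them. The counts changed when 1 sample was left out. Sex-linked expression differed between the 2 samples of each genotype (below), so each such fit was unbalanced for it between genotypes. The changes can thus not be put down to the left-out sample alone. The same holds for the list values with 1 sample left out below. Of the 24 named genes, Mgl2 and Naip5 passed in all 4 of these fits. The balance of higher and lower genes also turned with the scaling: 46.9% of the calls were higher as deposited, 24.1% (52 higher, 164 lower) with each array centred on the median of all probe sets, and 69.8% (44 higher, 19 lower) with each centred on the median of its tested genes.

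**Figure D1:**
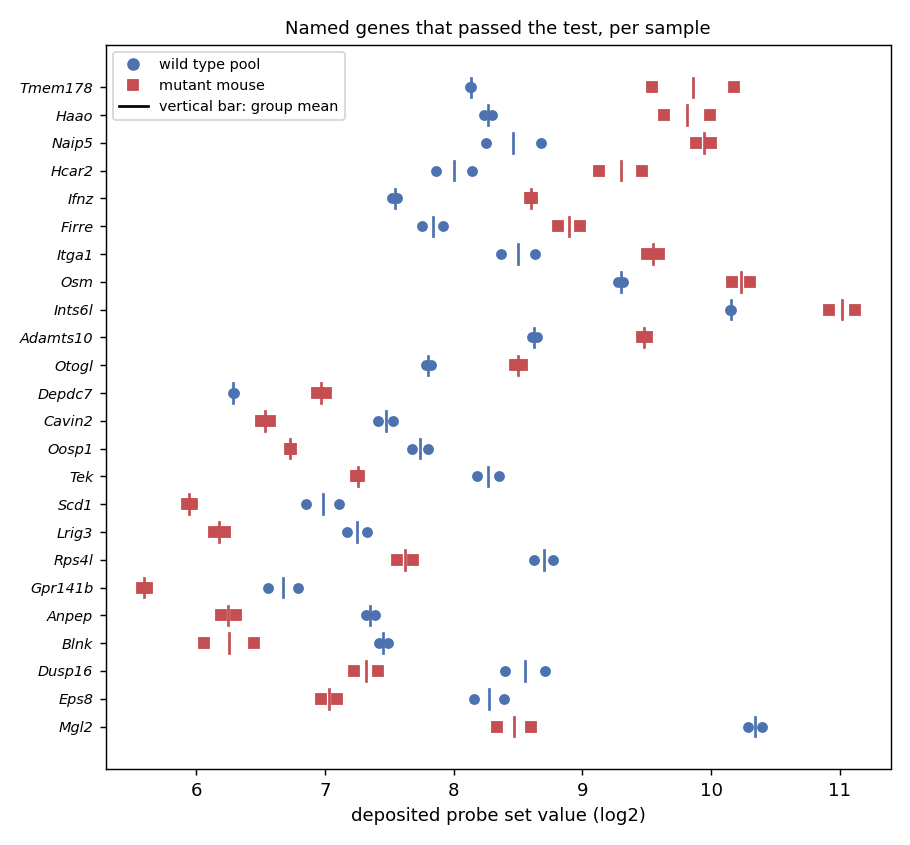
Deposited log2 values (horizontal axis) of the 24 named genes that passed the test, with 1 circle per wild type pool, 1 square per mutant mouse and a vertical bar at each group mean. Mgl2 has the largest fall (-1.87) and Tmem178 the largest rise (1.73), and in each gene both mutant mice lie on the same side of both wild type pools, which the naming rule required.

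By limma's camera test with a preset correlation of 0.01 between genes, PU.1-activated, granulocyte granule, immediate-early with heat shock, and interferon-stimulated genes were higher in the mutant, and stem cell, B cell, T and NK cell, erythroid and megakaryocyte genes were lower. With a correlation between genes estimated from the samples, camera called 0 of the 17 lists (lowest adjusted p = 0.390, and 0 at an unadjusted p under 0.05), against 4 higher and 5 lower with the preset one. Other myeloid lists, of monocyte and dendritic cell genes and of mast cell, basophil and eosinophil genes, did not pass with either. The version with an estimated correlation rests on only the 2 residual degrees of freedom, so few lists could pass with it. T and NK cell genes, with an estimated correlation of -0.04, went from an unadjusted camera p of 6.53e-04 to 0.0643. The estimated-correlation values, here and for each list below, thus cannot tell shared variation from low power. Only 2 list members passed the test over all genes without a block, Tek and Blnk, and the statements on single members below are for that fit. With the replicate number, which follows sex-linked expression, as a block, 24 of 448 distinct members were higher and 42 lower (limma, adjusted over all genes). That fit has fewer residual degrees of freedom than the main one and leans more on the prior variance. These included 8 granule genes higher, with Retnlg, Mmp8 and Mmp9 among them, Egr2 and Cxcl10 higher, 9 stem cell genes lower, with Mecom, Trpc6 and Ndn among them, and Ebf1, Dntt, Ncr1, Gzma, Pf4 and Vwf lower. The median difference over all tested genes was -0.07, so medians relative to it are given for lists past the threshold where the text names them as such. List members named beyond the 4 with the smallest p in each list were chosen after their values were seen. The fry test, which asks whether a list's genes move 1 way on balance, called 1 list, T and NK cell genes, and 7 at an unadjusted p under 0.05.

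PU.1-activated myeloid genes were higher as a list, with 30 of 37 members above 0 and a median difference of 0.22, or 0.29 relative to all genes (camera adjusted p = 4.05e-10, and adjusted p = 0.390 with an estimated correlation). No member passed over all genes, and 10 higher and 2 lower had an unadjusted p under 0.05 in limma. Adjusted over the list alone, 1 passed: Egr2, a zinc finger factor of macrophage differentiation, with a difference of 0.89. The fungal receptor Clec7a differed by 0.46, Ly86 by 0.38, Csf1r, the receptor for macrophage colony-stimulating factor, by 0.37, and the endotoxin receptor Tlr4 by -0.40. The list's relative median was 0.15 without mutant mouse 1, and 10 of its members also stood in other lists.

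Granulocyte granule genes were also higher as a list, with 22 of 25 members above 0 and a median difference of 0.28 (camera adjusted p = 8.27e-07, and adjusted p = 0.390 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 4 higher and 1 lower had an unadjusted p under 0.05 in limma. The largest differences were in Retnlg at 1.47 (SE 0.36), Ly6g at 1.45 (SE 0.61), the collagenase Mmp8 at 1.44 (SE 0.40) and the gelatinase Mmp9 at 1.15 (SE 0.37). Other members differed less, such as the antimicrobial genes Ngp by 0.36 and Camp by 0.28, the calcium-binding S100a8 by 0.17 and Itgb2l by 0.15. The primary granule genes Mpo and Elane differed by 0.03 and 0.05 at values near the top of the scale (13.90 to 13.97 for Mpo). Ms4a3 differed by -0.30. Wild type pool 1 exceeded pool 2 by a median of 0.48 over this list, and mutant mouse 1 exceeded mouse 2 by 0.35. The list's median relative to all genes, 0.36 with all samples, was 0.68 without wild type pool 1, 0.08 without pool 2, 0.12 without mutant mouse 1 and 0.62 without mouse 2.

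Immediate-early and heat shock genes, which respond quickly to signals and to handling of cells, were higher as a list, with 19 of 26 members above 0 and a median of 0.23 (camera adjusted p = 2.87e-08, and adjusted p = 0.390 with an estimated correlation). No member passed over all genes, and 12 higher and 2 lower had an unadjusted p under 0.05 in limma. Adjusted over the list alone, 9 were higher and 1 was lower. Beside Egr2, the antiproliferative gene Btg2 differed by 0.63 and the nuclear receptor Nr4a2 by 0.53. The heat shock genes Hsph1 and Hspa1a differed the other way, by -0.64 and -0.85.

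Interferon-stimulated genes were higher as a list, with 21 of 29 members above 0 and a median of 0.14 (camera adjusted p = 4.18e-06, and adjusted p = 0.580 with an estimated correlation). No member passed over all genes, and 3 higher had an unadjusted p under 0.05 in limma. Adjusted over the list alone, 1 passed, the chemokine gene Cxcl10. It measured 7.75 and 8.59 in the wild type pools and 11.31 and 10.10 in the mutant mice, a difference of 2.53 (SE 0.42, limma adjusted p = 0.0785 over all genes). The kinase gene Eif2ak2 differed by 0.30, Ifit3 by 0.32 and Ifit1 by 0.32. Without mutant mouse 1 the list's median relative to all genes dropped from 0.21 to 0.02 and the call was lost (camera adjusted p = 0.840), and without mutant mouse 2 it was 0.45.

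Stem cell and self-renewal genes were lower as a list, with 29 of 33 members below 0 and a median difference of -0.26, or -0.18 relative to all genes (camera adjusted p = 1.02e-05, and adjusted p = 0.390 with an estimated correlation). Tek fell over all genes, and adjusted over the list alone 17 members were lower and 1, Txnip, was higher (0.52). Mecom, a transcription factor of stem cell maintenance, differed by -1.02, the cation channel Trpc6 by -0.67, the growth suppressor Ndn by -0.66, and Procr, a surface marker of stem cells, by -0.66. The homeobox genes Meis1 and Hoxa9 differed by -0.56 and -0.40.

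B cell genes were lower as a list, with 22 of 24 members below 0 and a median of -0.23 (camera adjusted p = 0.00184, and adjusted p = 0.390 with an estimated correlation). Blnk fell over all genes, and adjusted over the list alone 11 were lower and 1, Cd72, was higher. Ebf1, the factor that starts the B cell programme, differed by -1.27, Dntt by -0.66 and the recombinase gene Rag2 by -0.58, whereas Ighm differed by 1.27 (SE 0.72). T and NK cell genes were lower by as much, with 19 of 22 below 0 and a median of -0.23 (camera adjusted p = 0.00184, and adjusted p = 0.390 with an estimated correlation). The fry adjusted p of 0.0391 for T and NK cell genes is against 0, and their median relative to all genes was -0.16. None passed over all genes, 12 lower had an unadjusted p under 0.05 in limma, and 9 were lower adjusted over the list alone. The natural killer receptor Ncr1 differed by -0.93, the granzyme Gzma by -0.57, Cd2 by -0.49 and Klrb1c by -0.36. These genes were dim, with wild type means from 5.17 (Klrb1c) to 6.44 (Ncr1). The medians over all probe sets were 7.06 and 7.14 in the wild type pools. Restricted to genes at or above the median level, both calls were lost (camera adjusted p = 0.634 for B cell and 0.863 for T and NK cell genes), and the relative median of T and NK cell genes turned to 0.02.

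Erythroid genes were lower as a list, with 27 of 29 members below 0 and a median of -0.25 (camera adjusted p = 0.00249, and adjusted p = 0.580 with an estimated correlation). None passed over all genes, 11 lower and 1 higher had an unadjusted p under 0.05 in limma, and 2 were lower adjusted over the list alone. The haem synthesis gene Alas2 differed by -0.55, Hemgn by -0.39, the transferrin receptor Tfrc by -0.36, Cldn13 by -1.11 (SE 0.31), and the erythroid factor Gata1 by -0.32. The median of erythroid genes relative to all genes was -0.17. It was -0.13 without wild type pool 2 and -0.08 without mutant mouse 2, where the call was lost (camera adjusted p = 0.0634 and 0.237), -0.27 without wild type pool 1 and -0.28 without mutant mouse 1.

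Megakaryocyte genes were lower as a list, with 18 of 21 members below 0 and a median of -0.17 (camera adjusted p = 0.0131, and adjusted p = 0.390 with an estimated correlation). None passed over all genes, 9 lower had an unadjusted p under 0.05 in limma, and 7 were lower adjusted over the list alone. Pf4, the platelet chemokine, differed by -0.75, von Willebrand factor (Vwf) by -0.51 and Rab27b by -0.39, whereas Thbs1 differed by 1.43 (SE 0.64). The call for megakaryocyte genes was lost without wild type pool 1 (camera adjusted p = 0.0623), without mutant mouse 2 (0.237), after quantile normalization (0.0564) and among genes at or above the median level (0.237). The median relative to all genes was -0.10 with all samples, -0.15 without wild type pool 1, -0.18 without mutant mouse 1 and -0.05 without mutant mouse 2.

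**Figure D2:**
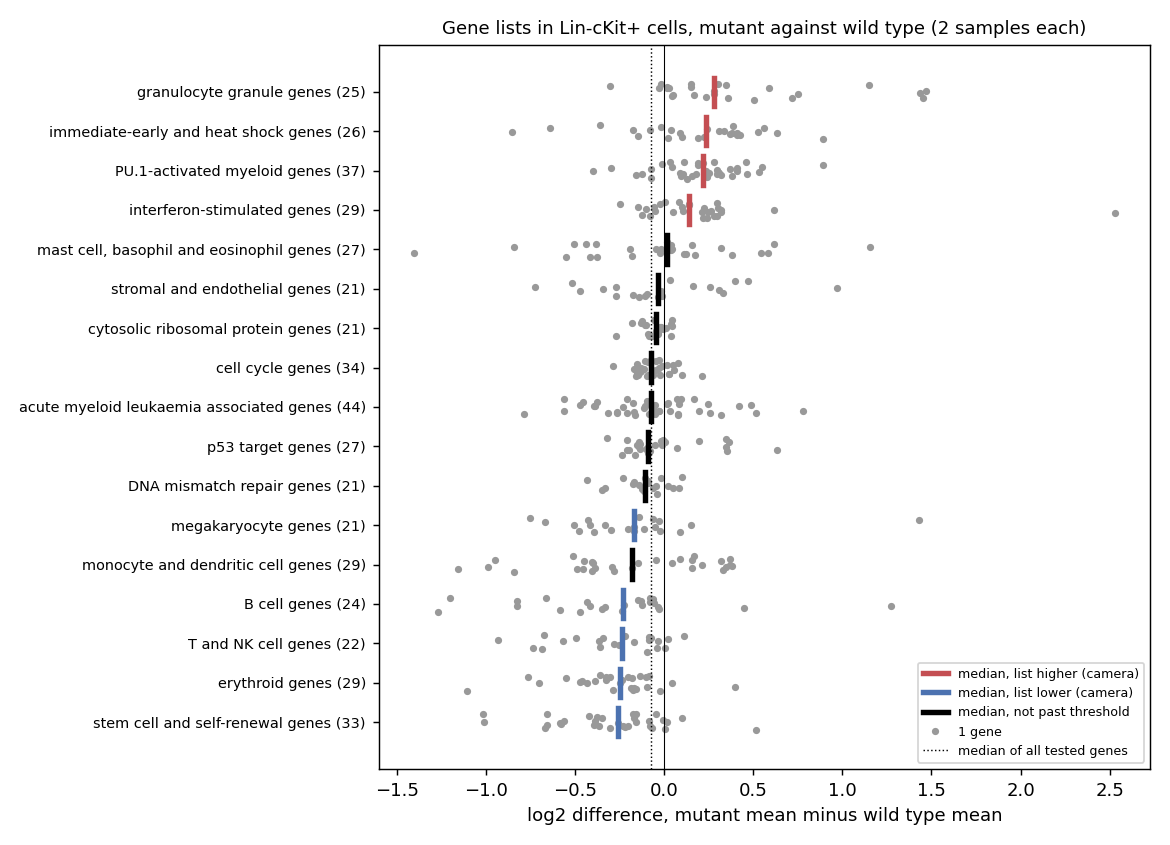
Log2 difference (horizontal axis, mutant mean minus wild type mean) of each gene, as points, in each list, with the list's median as a bar coloured by the camera test and the median of all tested genes (-0.07) as a dotted line. Medians of the lists past the threshold run from -0.26 for stem cell and self-renewal genes to 0.28 for granulocyte granule genes.

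Monocyte and dendritic cell genes did not pass as a list (camera adjusted p = 0.958), with 12 of 29 members above 0, 17 below and a median of -0.18. Without mutant mouse 1, monocyte and dendritic cell genes passed as lower (camera adjusted p = 0.00723). With all samples no member passed over all genes, and 6 higher and 12 lower had an unadjusted p under 0.05 in limma. Adjusted over the list alone, 5 were higher, among them Irf8 at 0.32 and Csf1r at 0.37, and 10 were lower, among them Ms4a6b at -0.51, the antigen presentation regulator Ciita at -0.49, the cytokine receptor Flt3 at -0.45 and H2-Eb1 at -0.84. Genes associated with acute myeloid leukaemia did not pass either (camera adjusted p = 0.940). No member passed over all genes, with 5 higher and 13 lower at an unadjusted p under 0.05 in limma. Adjusted over the list alone, 4 were higher and 8 lower, with Cd96 at -0.47, Havcr2 at -0.56 and Id1 at 0.78, while Kit differed by -0.08 and Myc by -0.05.

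The remaining lists did not pass in camera and had no member past the threshold over all genes. Their counts at an unadjusted p under 0.05 are to be set against the 4.03% higher and 15.3% lower of all genes. Mast cell, basophil and eosinophil genes had a median of 0.02 (camera adjusted p = 0.0590), with 4 higher and 3 lower at an unadjusted p under 0.05. As a list, mast cell, basophil and eosinophil genes passed as higher after quantile normalization (camera adjusted p = 0.0253), after centring on the median of all probe sets (0.0105) and without mutant mouse 2 (4.02e-06). The chemokine receptor Ccr3 differed by 1.16, the histamine enzyme Hdc by -0.41, Siglecf by -0.55 and Ms4a2 by -0.37. Stromal and endothelial genes had a median of -0.03 (camera adjusted p = 0.539), with 2 higher and 5 lower at that level. Without mutant mouse 1, stromal and endothelial genes passed as higher (camera adjusted p = 0.0236). Emcn differed by -0.72, Ibsp by 0.40, Postn by -0.34 and Bgn by -0.51. Cell cycle genes had a median of -0.07 (camera adjusted p = 0.958), with 1 higher and 1 lower, Mki67 at 0.21 and Aurka at -0.29. Mcm7 differed by -0.17 and Tyms by -0.15. DNA mismatch repair genes other than Msh2 had a median of -0.11 (camera adjusted p = 0.327), with 4 of 21 lower at that level where 3.20 would be expected from all genes. Msh6, the partner of Msh2 in mismatch recognition, differed by -0.35, Mlh3 by -0.43, Pms1 by -0.33 and Pold2 by -0.23. Targets of p53 had a median of -0.09 (camera adjusted p = 0.393), with 5 higher and 1 lower. Btg2 differed by 0.63, Pmaip1 by 0.36, Fas by 0.35 and Perp by 0.355. Cytosolic ribosomal protein genes had a median of -0.045 (camera adjusted p = 0.982), with 1 lower. Rps19 differed by -0.27, Rps3 by -0.18, and Rplp1 and Rpl13 by -0.13 each. The median and the mean differed in sign for mast cell genes (mean -0.04), and the median and the camera direction differed in sign for stromal and endothelial, p53 target, acute myeloid leukaemia associated and ribosomal protein genes.

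Samples with the same replicate number shared their sex, as read from sex-linked genes. Xist, expressed from the inactive X chromosome of females, measured 11.86 in wild type pool 1 and 12.17 in mutant mouse 1, against 5.53 in pool 2 and 5.11 in mouse 2. The Y-linked genes Uty, Kdm5d and Eif2s3y ran the other way, with Eif2s3y at 4.91 and 4.73 in the samples numbered 1 and at 9.68 and 9.90 in those numbered 2. By these genes each genotype held 1 female sample, numbered 1, and 1 male sample, numbered 2. Sex was thus balanced between genotypes, and it was not in the main fit. No sex-linked gene passed between genotypes in limma (0 at an unadjusted p under 0.05). With this split, which follows the replicate number, as a block in the fit, limma called 275 genes higher and 473 lower, with all 49 among them. The block fit has fewer residual degrees of freedom than the 2 of the main fit. Its calls thus rest more on the prior variance shared across genes. Within number 1 the median difference was 0.31 for PU.1-activated, 0.21 for granule, 0.33 for immediate-early and heat shock and 0.31 for interferon-stimulated genes. Within number 2 these were 0.11, 0.22, 0.07 and 0.02. Among the lists that were lower, the medians within numbers 1 and 2 were -0.32 and -0.23 for stem cell, -0.19 and -0.24 for B cell, -0.25 and -0.22 for T and NK cell, -0.05 and -0.44 for erythroid and -0.13 and -0.26 for megakaryocyte genes. Each of these rests on 1 sample per genotype and was not tested.

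**Figure D3:**
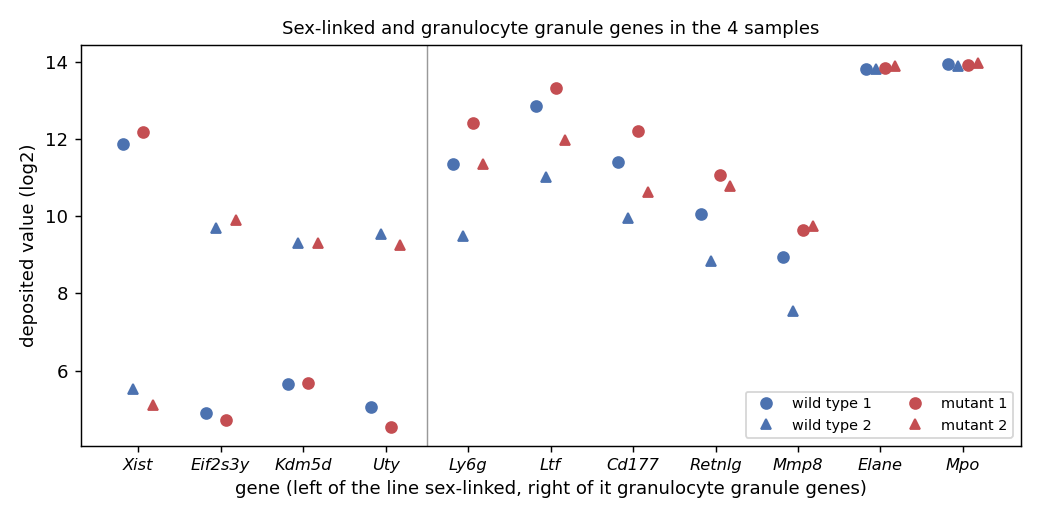
Deposited log2 values (vertical axis) of sex-linked genes, left of the line, and granulocyte granule genes, right of it, in each of the 4 samples. Xist is at 11.86 and 12.17 in the samples numbered 1 and at 5.53 and 5.11 in those numbered 2, and Ly6g runs from 9.49 in wild type pool 2 to 12.40 in mutant mouse 1.

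A permutation test cannot pass in this design, since the smallest two-sided exact p for 2 samples against 2 is 0.333, so the calls rest on limma's model across genes. Each mutant sample is 1 animal, and background strain was mixed in both groups.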

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

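The tests of scaling and of the median shift below were chosen after the result was seen, and the test on single probe sets was set before its value was known. Probe sets outside the tests of genes, those with no single gene in the annotation used, differed more often than those with a gene: 435 of 13767 (3.16%) were higher in the mutant than in wild type and 6 were lower (limma, adjusted over all 35556 probe sets). Of the 21789 probe sets with 1 gene, 22 were higher and 20 lower in the same fit. The median difference of the 435 was 1.40 on the log2 scale. This balance depends on the scaling. The medians of the unnamed probe sets were 6.45 and 6.52 in the wild type pools and 6.72 and 6.77 in the mutant mice, and with each array centred on that median, a setting also chosen after the result was seen, 1126 were higher and 3871 lower. This centring lowers the mutant minus wild type difference of every probe set by 1 constant, while the median difference of unnamed ones was 0.04 before it. The lower calls thus follow largely from that constant, and the 1126 do not reflect larger differences.

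These 435 were in different parts of the table, 138 among the 6617 probe sets that precede the first named one and 297 among the other 7150. Over all probe sets with no single gene the median difference was 0.04, against -0.07 for those with a gene. A scaling that depends on signal level alone is argued against, since at matched level they lay on average 0.147 (bootstrap SD 0.0041) above probe sets with a gene. The excess varied with level, from 0.02 at a log2 value of 4 to 4.5 to 0.25 at 7 to 7.5, and was 0.01 at 10.5 to 11 and -0.02 at 11.5 to 12. Genomic DNA or background that raises silent sequences stays open for this general shift. Olfactory receptor genes, which these cells are not known to use, showed 0.603 of the average excess. The averages weigh the levels differently, since olfactory genes were dimmer, so this ratio is not matched for level. At 4.5 to 5 the median difference was 0.036 for olfactory and 0.034 for unnamed probe sets. At 6 to 6.5 it was 0.012 and 0.093. For the single probe sets that passed, 0 of 1035 olfactory receptor probe sets were called higher (limma, 43 higher and 13 lower at an unadjusted p under 0.05). At the share of unnamed probe sets of the same level 31.0 were expected (exact Poisson p = 3.47e-14, which takes probe sets as independent). This argues against a background that raises all silent sequences alike, only if unnamed probe sets respond as olfactory ones do. That was not checked, so background is not excluded for them. The mutant genotype, or single animals against pools, remains a candidate source of these single probe sets, untested because what they target is not given in the annotation used.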

How the results depend on the processing

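Centring on the median of tested genes, and centring of unnamed probe sets on their own median, were chosen after the data were seen. Of 1229 comparisons of named genes with an alternative, 1095 kept direction and side of the threshold, 54 lost and 69 gained the call and 11 reversed. Of 255 for lists, 210 kept both, 25 lost and 5 gained the call and 15 reversed. Reversed genes were sex-linked, and the reversed lists included 1 that passed as reported, T and NK cell genes. Spi1 stayed below wild type and short of the threshold in all settings. Mgl2 passed in each.

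Genes higher and lower, 23 and 26 as reported, were 52 and 164 after centring on the median of all probe sets (24.1% higher, against 46.9%), 44 and 19 after centring on tested genes (69.8% higher), which moves the median over genes from -0.07 to 0.03, and 7 and 7 at or above the median level, where fewer genes are tested. The prior variance trend gave 42 higher, the robust prior 41 and 63, a test of all probe sets 457 higher, mostly unnamed ones, and the 2-fold limit 13 and 12. With 1 sample left out, the range was 9 to 81 higher and 3 to 53 lower, where a lone sample is assumed to vary like the other group. Sex-linked expression was then also unbalanced between genotypes. The labels do not say what the replicate number stands for, and same-numbered samples shared their sex-linked expression. Their deviations correlated at 0.33 (0.22 without sex-linked genes). With the number as a block, a fit with fewer residual degrees of freedom, 275 genes were higher and 473 lower. All 49 reported genes were among them, and 9 lists passed. Lists past the threshold, 9 as reported, were 0 with an estimated correlation, tested on 2 residual degrees of freedom, and 1 with fry, which compares with 0. The cause was not tested in the other cases. The count of unnamed probe sets higher, 435, was 1126 after centring on their own median, with 3871 lower, a setting that lowers all their differences by 1 constant.

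List medians relative to all genes reversed after quantile normalization for cell cycle genes (0.0651), DNA mismatch repair genes (0.0295) and acute myeloid leukaemia associated genes (0.0481). At or above the median level they reversed for monocyte and dendritic cell genes (0.128), T and NK cell genes (0.0222), cell cycle genes (0.0094) and acute myeloid leukaemia associated genes (0.0324). Centring on all probe sets turned Kdm5d to -0.0447 and Eif2s3y to -0.0438, and centring on tested genes turned Xist to 0.0513. With 1 sample left out, Uty ran from -2.77 to 1.95, Xist from -3.58 to 3.48, Kdm5d from -1.81 to 1.84 and Eif2s3y from -2.57 to 2.60. The same ranges were -0.0161 to 0.0612 for stromal and endothelial genes, -0.0213 to 0.0304 for cell cycle genes, -0.0368 to 0 for DNA mismatch repair genes, -0.0244 to 0.0291 for p53 target genes, -0.0456 to 0.0414 for acute myeloid leukaemia associated genes and -0.0055 to 0.0349 for cytosolic ribosomal protein genes. The cause was not tested. A pseudocount was not applied, since values were already log2, and Msh2 had no value. Signal over background was not given, so dim genes have no stated limit.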

Other observations

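The inflammatory, MHC class II and lymphoid progenitor groups, the small RNA counts, and the tests on granule genes and on neighbours of Msh2 were chosen after the results were seen. The 3 groups were put together from differences already seen, so they are described by their values and no test of a group is given. Of 18 inflammatory cytokine and feedback genes, 16 lay above 0, with a median difference of 0.48. Osm was the 1 member past the threshold over all genes. Il1b differed by 1.34 (limma adjusted p = 0.0507), Acod1, which makes the macrophage metabolite itaconate, by 1.497, the prostaglandin synthase Ptgs2 by 0.82, the signalling inhibitor Socs3 by 0.80 and Tnf by 0.73. The group's median was 0.76 between the samples numbered 1 and 0.24 between those numbered 2.

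Of 9 genes of antigen presentation on MHC class II, 8 lay below 0, with a median of -0.49. None passed limma's test over all genes, and 5 lower had an unadjusted p under 0.05. H2-Aa differed by -1.16 (SE 0.25), Cd74 by -0.99 (SE 0.40) and H2-Ab1 by -0.95 (SE 0.21), while H2-DMa differed by 0.06. Of 14 lymphoid progenitor genes, 11 lay below 0, with a median of -0.52. Blnk fell over all genes, Cd7 differed by -0.996 (SE 0.16), Il7r by -0.83 and Rag1 by -0.82. Notch1 differed by 0.27 and Ighm by 1.27 (SE 0.72). These members were partly those of the B cell list.

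Small RNA genes were outside the naming rule. Among genes past the threshold, the largest difference was in Mir680-1, from 6.24 ± 0.01 to 8.76 ± 0.12 (SD, n = 2 each), a rise of 2.52 (limma adjusted p = 0.00132), and Mir680-2 rose by 1.96 (limma adjusted p = 0.00361). Mir142, a microRNA of blood cells, rose by 1.34. Of 31 small nucleolar RNA genes of the Snord class, 3 rose and 0 fell in limma, and of 291 microRNA genes 4 rose and 0 fell. Of 20 genes of the Snora class 0 rose and 1 fell, Snora44, with a difference of -1.62 (limma adjusted p = 0.0418), and the small RNA gene Rny3 fell by 0.87. At an unadjusted p under 0.05 in limma, 15 were higher and 6 lower in the Snord class, 5 and 5 in the Snora class, and 39 and 12 among microRNA genes. These short targets are read from few probes, and a total RNA amplification reads precursors or host transcripts rather than mature microRNAs.

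Granulocyte granule genes were higher in the mutant, with a median difference of 0.283 (camera adjusted p = 8.27e-07, and adjusted p = 0.390 with an estimated correlation), and no member passed in limma without a block, with 4 higher and 1 lower at an unadjusted p under 0.05. The list's mean difference was 0.406 as deposited and 0.421 after quantile normalization. It was 0.346 (SE 0.0995 over genes, not over samples) after centring on all probe sets and 0.509 after centring on tested genes. Centring shifts all genes of an array by 1 constant, so its result follows from the array medians. None of these scalings removed the difference, and a scaling error of another form was not tested. A share of mature granulocytes that varies between samples irrespective of genotype stays open. The gap between the wild type pools, a median of 0.475, cannot decide it. Mutant mouse 1 exceeded mouse 2 by 0.35, so the gap followed the replicate number and sex-linked expression in both genotypes. Within numbers 1 and 2 the genotype difference was 0.21 and 0.22, each from 1 sample per genotype. With the number as a block, limma called 8 members higher and 0 lower. The abundant granulocyte genes S100a8, Camp and Ngp measured 13.38, 13.33 and 13.30 in wild type pool 1 and 13.14, 12.68 and 12.72 in pool 2, and the sort for lineage-negative cells would remove mature granulocytes. Of the 25 genes 1 stood in another list, and early progenitors also express several of them, such as Mpo and Elane. A shift in maturation with genotype is a further open hypothesis that was not tested.

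Tmem178 and Haao, which both rose, lie on the chromosome of Msh2, with 35 and 27 tested genes between each and Msh2. A candidate explanation is flanking DNA carried along with the targeted Msh2 allele in a mixed background. It stays open, because the position of these genes prompted the question. Up to 50 tested genes on either side of Msh2 gave 60 others, with fewer than 50 on 1 side. By limma's threshold they are too few to decide: 0 passed where 0.142 would be expected. At an unadjusted p under 0.05 in limma, 2 were higher and 18 lower (2.42 and 9.15 expected). This excess of lower genes was not tested, and Tmem178 and Haao rose. Around Spi1, the other altered locus, 1 of the 200 tested genes within 100 on either side passed, Depdc7, where 0.492 would be expected. An effect of the loss of Msh2 itself was not tested.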
